A study of Mus musculus with 4 samples.

How the data were processed

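RNA was measured in 4 mammary gland tumours of 1 genotype, MMTV-R26Met. Per the labels' protocols, poly-A RNA was purified, fragmented, copied by random priming, amplified and sequenced as paired reads on a NovaSeq X. The authors deposited 1 table of whole-number counts per gene for the 4 tumours, and no normalization had been applied to these deposited counts, which sum to different totals per library. Per the submitters' processing notes, FastQC and the genome builds GRCm38 and mm10 were used. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies carry uncertain counts. Random priming and poly-A selection make a gene's count depend on transcript length, so levels of different genes are compared only loosely, while tumours are compared gene by gene.

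Rows of the table are Entrez gene numbers. Of 28440 rows, 24480 (86.08%) were matched to a symbol in the RefSeq table of assembly GRCm38.p6, and these rows held 97.86% of the counts. The 3960 rows without a symbol stayed in the library sizes and tests. The number of columns of per-sample values not used was 0. Each library column carried the tumour's number, which gave its sample.

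Library totals were 42809015, 35220504, 36885892 and 41756363 counts, so 3 counts, the limit that a count of 0 allows, correspond to 0.0708, 0.0868, 0.0784 and 0.0733 CPM. Exact binomial intervals (95%) are given for shares of counts in single libraries and cover counting error only. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with 1 group (a count cutoff of 10 at the median library size in all 4 libraries and 15 counts in total), which left 15808 genes, and libraries were scaled by TMM. Since no groups are compared, no quasi-likelihood test of a contrast exists. Each gene was given an intercept-only negative binomial fit at the trended dispersion, and its deviance was compared with the chi-square distribution, with Benjamini-Hochberg adjustment over all genes tested (threshold 0.05). A gene that passes is more variable between tumours than genes of like expression. The common biological coefficient of variation was 0.411, and the trend ran from 0.331 to 0.514. CPM are TMM-scaled values, and log2 CPM used a prior count of 2.

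Before the data were examined, 41 gene lists with 663 memberships were fixed, of which 652 were measured. A list's score in a tumour is the mean over tested members of log2 CPM minus the gene's mean over the tumours. The SD of the 4 scores was compared with 10000 random lists of the same size matched on mean expression in 20 bins (one-sided permutation p, smallest value 1e-04, Benjamini-Hochberg over lists). A low p says that the members moved together, since random genes are less correlated than co-regulated ones. Enrichment of list members among genes past the first test was tested by a one-sided Fisher's exact test against all genes tested. Fisher's exact test treats genes as independent, so its p is too small for lists whose members are co-regulated. Lists needed at least 5 tested members, which 35 of 41 had. Of these, 18 passed the score test and 8 the enrichment test, and the same 8 passed both.

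The genes named in the text were set by a rule fixed at the same time. It took a panel of receptors, drivers and immune genes, the member of each list with the highest mean and the tested member with the largest SD, the 10 genes past the test with the largest SD, the genes highest (5) and lowest (3) in each tumour relative to the nearest other tumour (mean CPM of at least 5), and the 10 genes with the highest mean. Predicted genes, pseudogenes and receptor segments were skipped, 6 in all in the choice by tumour. The rule gave 134 genes, of which 58 passed the test and not all are described; some are not reported here. Other list members are named as examples after their values were seen, as are Ptprc and the genes outside the lists in the closing section.

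The gene test was checked on simulated counts with the means, dispersions and library sizes of these 4 libraries and 1 library raised per changed gene. It found 26.5% of 49 genes raised 4-fold, 68.1% of 47 raised 8-fold, 90% of 50 raised 16-fold and 98% of 50 raised 32-fold, and passed 7 of 15208 unchanged genes. With no gene changed, 0 of 15425 passed. The list test found 10 of 10 simulated lists shifted 2-fold in 1 library and called 0 of 30 unshifted lists. Simulated genes were drawn independently of each other and at the trended dispersion. These checks therefore do not give the rate of false calls among co-expressed genes or genes whose dispersion departs from the trend.

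Alternatives were other scalings (RLE and library size alone), no count filter, a mean of at least 5 CPM, Holm adjustment, DESeq2 1.42.0 dispersion outliers, other prior counts (0.5 and 5), medians in place of means, lists without their most variable member, random lists matched also on SD, the milk, fat and muscle lists and the 100 most abundant genes left out, and each tumour left out in turn. A count cutoff needed in at least 1 library was added after the data were seen. Correlations across tumours are not reported, since 4 tumours are too few. For the closing section, GC content and length were taken from the longest GENCODE vM21 transcript of each Entrez gene (85.1% of tested genes), and chromosome medians used 11469 genes with a mean of at least 5 CPM on the autosomes and X. The chromosome medians were checked on counts of these genes simulated in the same way, each gene drawn independently. With no chromosome changed their mean absolute value was 0.026, and with chromosome 4 raised 1.5-fold in tumour 4 the median of that chromosome was 0.441. Figures were drawn with matplotlib 3.10.9.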

Results

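Bulk poly-A RNA sequencing was done on 4 mammary gland tumours, numbered 1 to 4, of MMTV-R26Met mice, a model of triple-negative breast cancer in which a Met transgene at the Rosa26 locus is switched on in the mammary gland. The 4 libraries form 1 group, with no treated, normal or control tissue among them, so the design asks what these tumours express and how far they differ from one another. The libraries of tumours 1 to 4 held 42809015, 35220504, 36885892 and 41756363 counts. Each pair of libraries differed far beyond counting error, with a chi-square per degree of freedom from 132 to 387. No library was therefore a copy of another, and each was used as a separate sample. This check covers counting error only and does not show that the tumours are independent. The labels do not say whether the tumours came from separate mice, and p-values therefore describe these 4 tumours only. Those of edgeR set a gene's spread between the tumours against the trend over genes. The permutation and Fisher's exact p of lists compare list members with other genes, not tumours with one another.

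Met, the receptor of hepatocyte growth factor and the transgene of this model, was among the most abundant transcripts in every tumour. Counts per gene cannot tell any reads of the transgene from those of the Met gene on chromosome 6. Met (Entrez gene 17295, chromosome 6, 17463349 to 17573980, GRCm38) reached 3755, 2386, 2454 and 1800 CPM (counts scaled to library size) in tumours 1 to 4, a mean of 2599 ± 825 (SD, n = 4), and ranked 13, 18, 15 and 28 among genes. Its ligand Hgf stayed at 5.52 ± 1.46 CPM (SD, n = 4). Transcripts of the hormone receptors were scarce. Esr1, the oestrogen receptor, had 8.14 ± 5.81 CPM (SD, n = 4), and Pgr, the progesterone receptor, had 34 and 79 counts in tumours 1 and 3 and 0 counts in tumours 2 and 4, which allows up to 0.0868 and 0.0733 CPM. Erbb2 stood at 112 ± 23.8, Egfr at 108 ± 51.4 and Erbb3 at 322 ± 28.9 CPM (SD, n = 4). Of 16 tested members of the MET axis list 1 differed between tumours more than genes of like expression, also 1 when adjusted over the list alone. That member was Spint1, an inhibitor of the proteases that activate Hgf, at 13.4 CPM in tumour 1 and 110 CPM in tumour 2 (edgeR adjusted p = 0.00232). The receptor list also had 1 of 16, and 1 adjusted over the list alone, the neurotrophin receptor Ntrk2, at 79.6 CPM in tumour 1 and 9.41 in tumour 3 (edgeR adjusted p = 0.0038). Both calls were lost without tumour 1 (edgeR adjusted p = 0.529 and 0.634). As lists, neither the MET axis (score SD 0.21, adjusted permutation p = 0.163) nor the receptors (0.12 and 0.539) passed the score test. The MET axis list did pass without tumour 4 (adjusted permutation p = 0.0486) and with medians over members (0.0404).

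The epithelial keratins Krt8 and Krt18 stood at 1074 ± 201 and 961 ± 190 CPM (SD, n = 4), and Epcam at 620 ± 152 CPM. The most abundant transcript of every library was assigned to Siglece, a sialic acid binding lectin of myeloid cells, at 32580 ± 6165 CPM (SD, n = 4), whereas the pan-leukocyte gene Ptprc, chosen for comparison after its values were seen, had 67.4 to 93.6 CPM. Whether these reads came from Siglece itself or from other sequence shared with it cannot be told from counts per gene. After Siglece the most abundant named genes were the nuclear RNA Malat1 (14630 ± 1012 CPM), Trf, which encodes transferrin (9585 ± 4293 CPM), Neat1 (9057 ± 3310 CPM) and the translation factor Eef1a1 (8535 ± 2320 CPM), each as mean and SD over the 4 tumours. Trp53, Myc and Brca1 had 74.59 ± 16.96, 64.43 ± 16.01 and 43.76 ± 27.98 CPM (SD, n = 4), and none of these 3 genes passed the test described next.

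To find the genes that set single tumours apart, 15808 genes were tested for a spread between tumours above that of genes with like expression. Of these, 574 (3.63%) passed at an adjusted p of 0.05. Their median fold from the lowest to the highest tumour was 15.7, against 1.72 over all genes tested. Each of the 574 genes was assigned to 1 tumour as highest or lowest, whether or not that tumour stood clearly apart. Oas2, for example, had 13.1, 128, 8.91 and 167 CPM in tumours 1 to 4. The assigned tumour was most often 3 or 4. As highest, 134 genes were assigned to tumour 3, 113 to tumour 4, 47 to tumour 1 and 25 to tumour 2. The genes assigned as lowest numbered 120, 81, 37 and 17 in tumours 4, 3, 1 and 2. Across genes, which are not independent replicates, tumours 1 and 2 had the highest Spearman correlation of the 6 pairs (0.963) and tumours 3 and 4 the lowest (0.911). Between tumours 3 and 4, 3198 of 14630 genes with a mean of at least 1 CPM were over 2-fold apart, against 1492 between tumours 1 and 2. Without tumour 4 the number of genes past the test was 367. DESeq2's rule for dispersion outliers marked 91 genes, each of them among the 574. Of the 58 named genes past the test, 11, 17, 18 and 11 lost the call when tumour 1, 2, 3 or 4 was left out. Many of them were named because 1 tumour stood apart, so such losses are partly built in.

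Of the 35 lists tested, milk protein genes had the widest spread between tumours. Their list score, the mean log2 CPM of the members relative to the mean of the tumours, was 3.30 in tumour 4 and 0.43 in tumour 2, against -1.41 in tumour 3 and -2.31 in tumour 1. Of 14 tested members 11 passed the test, and 13 adjusted over the list alone, among them the caseins Csn1s1, Csn1s2a, Csn1s2b, Csn2 and Csn3, the whey protein Wap, Lalba, which encodes alpha-lactalbumin, and lactoferrin (Ltf). Csn2 had 8476 CPM in tumour 4 and 22.6 to 490 CPM in the others (edgeR adjusted p = 5.56e-18). Wap had 102 CPM in tumour 4 and at most 2.55 elsewhere (edgeR adjusted p = 5.28e-24), and Glycam1 ran from 2.33 CPM in tumour 3 to 3262 in tumour 4 (edgeR adjusted p = 5.74e-25). Of the 14 tested members 12 were highest in tumour 4, the exceptions being Lalba (522 CPM in tumour 2) and Trf. The order of the other tumours varied, and 5 members had the order of the list score. Csn1s1, Ltf and Btn1a1 were higher in tumour 3 (1780, 752 and 47.3 CPM) than in tumour 2 (859, 416 and 15.5 CPM), and 5 members, Glycam1 and Muc15 among them, were lowest in tumour 3 and not in tumour 1. The list held 5.08% of all counts in tumour 4 (95% exact binomial interval 5.07 to 5.08%), 2.23% in tumour 2, 1.15% in tumour 3 and 1.13% in tumour 1. Trf, also a member, held most of these counts in tumours 1, 2 and 3, did not pass the test and was lowest in tumour 4 (5531 CPM) and highest in tumour 2 (15210 CPM). Without Trf the list held 4.53, 0.737, 0.421 and 0.0894% of the counts of tumours 4, 2, 3 and 1. Such intervals cover counting error only. The score SD of 2.48 had a permutation p of 1e-04, the smallest the random lists can give (adjusted 0.000437), and members were enriched among genes past the test (Fisher's exact test, adjusted p = 1.52e-12). The latter counts genes as independent, which members that move together are not. Of the members named, Csn3 did not pass without tumour 1, Lalba without tumour 3 and Csn1s2b without tumour 4 (edgeR adjusted p = 0.089, 0.541 and 1), and Wap was too scarce to be tested without tumour 4.

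Basal and luminal epithelial genes also differed between the tumours. Basal genes scored 1.06 in tumour 4 and -0.65 to -0.04 in the others, and 5 of 16 passed the test, or 6 adjusted over the list alone. The basal keratins Krt5 and Krt14 had 87.3 and 89.9 CPM in tumour 4, against at most 4.08 and 28.4 CPM elsewhere (edgeR adjusted p = 1.47e-15 and 3.86e-08). Trp63, a transcription factor of basal cells, Col17a1, a hemidesmosome collagen, and Oxtr, the oxytocin receptor, were likewise highest in tumour 4, at 46.6, 30.3 and 35.6 CPM. The contractile genes of the same list did not pass, with Acta2 at 63.2 and Tagln at 38.3 CPM in tumour 4 against 73.0 to 112 and 36.3 to 71.6 CPM in the others. Luminal genes scored 0.43 and 0.32 in tumours 2 and 4 and -0.54 and -0.22 in tumours 1 and 3. Of 17 tested members 4 passed, or 5 adjusted over the list alone, namely Krt19 (11.6 CPM in tumour 1 and 371 in tumour 4), Muc1, Gata3 (4.13 CPM in tumour 3) and Spdef (28.1 CPM in tumour 2). Squamous differentiation genes passed in 3 of 6 tested, also 3 adjusted over the list alone, with Tgm1 and Sbsn high in tumours 2 and 4 and Krt6a in tumour 4. The score SDs were 0.75 for basal, 0.46 for luminal and 0.64 for squamous genes (adjusted permutation p = 0.000437, 0.0021 and 0.0304), and enrichment gave adjusted p = 0.0017, 0.014 and 0.00614 by Fisher's exact test. Without tumour 4 the basal list passed neither test (adjusted permutation p = 0.0679, Fisher's exact test 0.558), and Krt5, Trp63, Col17a1 and Oxtr did not pass (edgeR adjusted p = 0.644 for Krt5 and 1 for the others). The squamous score call was lost without tumour 2 or 4 (adjusted permutation p = 0.0513 and 0.155), without its most variable member (0.209), against random lists matched also on SD (0.229) and with the count minimum required in 1 library (0.0584), where its enrichment was lost too (Fisher's exact test, adjusted p = 0.191). Without tumour 3 the luminal enrichment had adjusted p = 0.0553 by Fisher's exact test, and Gata3 had edgeR adjusted p = 1, against 0.0566 without tumour 4. Without tumour 2 Spdef had edgeR adjusted p = 0.217, and Krt6a was lost without tumour 1, 2 or 4 (0.394, 0.132 and 0.782).

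Interferon response genes were highest in tumour 4 and lowest in tumour 3. The type I interferon list scored 1.20 in tumour 4, 0.51 in tumour 2, -0.43 in tumour 1 and -1.28 in tumour 3, and 6 of 18 members passed the test, or 16 adjusted over the list alone. Oas2, an antiviral RNA sensor, had 167 CPM in tumour 4 and 8.91 in tumour 3 (edgeR adjusted p = 2.31e-08), and Rsad2 had 296 and 36.6 CPM (edgeR adjusted p = 8.91e-05). MHC class I presentation took the same order of tumours, with scores of 0.95, 0.50, -0.28 and -1.17 in tumours 4, 2, 1 and 3. Of 14 members 5 passed, or 8 adjusted over the list alone. They were H2-K1, H2-D1, H2-Q4, the peptide transporter Tap1 and Nlrc5, the transactivator of the class I genes, which ran from 8.76 CPM in tumour 3 to 181 in tumour 4 (edgeR adjusted p = 4.78e-06). H2-K1 ran from 165 to 2127 CPM between the same tumours (edgeR adjusted p = 0.00158). The class I genes have near-identical copies, so their separate counts are uncertain. MHC class II and gamma interferon genes scored 0.94 in tumour 4 and 0.29 in tumour 2, with tumours 1 and 3 close together at -0.58 and -0.66. Of 16 members 4 passed, or 5 adjusted over the list alone. Those 4 were the interferon-induced GTPases Gbp2, Gbp4, Iigp1 and Igtp. Gbp4 was lowest in tumour 1 (3.18 CPM) and Iigp1 in tumour 3 (51.8 CPM). Gbp2 had 623 CPM in tumour 4 and 62.0 to 113 CPM in the others. The class II genes themselves did not pass, with Cd74 at 285 ± 120 CPM (SD, n = 4). All 3 lists had an adjusted permutation p of 0.000437, with score SDs of 1.08, 0.93 and 0.76, and were enriched by Fisher's exact test (adjusted p = 0.000499, 0.0011 and 0.0129). Without tumour 3 these enrichments were lost (Fisher's exact test, adjusted p = 0.0553, 1 and 0.0553), as were the calls of H2-K1, H2-D1, H2-Q4, Tap1, Nlrc5 and Iigp1 (edgeR adjusted p = 0.323, 0.518, 0.276, 0.756, 0.135 and 0.616). Without tumour 4 the class II list had adjusted p = 0.558 by Fisher's exact test, and Gbp2, Gbp4, Igtp and Tap1 did not pass (edgeR adjusted p = 1, 0.905, 0.356 and 0.196). Gbp4 and Tap1 were lost without tumour 1 as well (0.436 and 0.0552), and Tap1 without tumour 2 (0.0551).

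Of the leukocyte lists tested, neutrophil genes had the widest spread between tumours. They scored 1.19 in tumour 3, 0.27 in tumour 4, -0.67 in tumour 1 and -0.79 in tumour 2 (score SD 0.92, adjusted permutation p = 0.000437). Of 9 tested members 1 passed, or 3 adjusted over the list alone. That gene, S100a9, had 31.5 CPM in tumour 3 and 2.63 in tumour 2 (edgeR adjusted p = 0.0183). Csf3, the growth factor of neutrophils, was also highest in tumour 3, at 18.4 CPM, and was the 1 of 10 tested recruiting ligands that passed (edgeR adjusted p = 0.00519), with 2 adjusted over the list alone. Both calls were lost without tumour 2 (edgeR adjusted p = 0.179 and 0.108) or tumour 3 (1 and 0.408). The neutrophil list was not enriched among genes past the test (Fisher's exact test, adjusted p = 0.743). Its most abundant member, Lcn2, did not take the order of the list score, with 6509, 4449, 3269 and 2657 CPM in tumours 1 to 4. Suppressive myeloid genes scored 0.64 and 0.47 in tumours 3 and 4 and -0.41 and -0.70 in tumours 1 and 2 (score SD 0.65, adjusted permutation p = 0.00377, and 0.0584 with the count minimum required in 1 library only). In that list 2 of 11 passed, also 2 adjusted over the list alone, with Chil3 highest in tumour 3 and Ptgs2, which makes prostaglandins, in tumour 4 at 40.7 CPM. Chil3 was lost without tumour 2 or 3 (edgeR adjusted p = 0.162 and 0.166) and Ptgs2 without tumour 2 or 4 (0.173 and 0.564). Macrophage genes had a score SD of 0.27 (adjusted permutation p = 0.048), a call lost when tumour 1, 2 or 3 was left out (0.0866, 0.109 and 0.0555) and under RLE scaling or library size alone (0.0504 and 0.0738). Of 17 macrophage genes 1 passed, also 1 adjusted over the list alone, Gpnmb at 74.5 CPM in tumour 4 (edgeR adjusted p = 0.0158, and 0.0743 and 1 without tumours 2 and 4). T cell genes did not pass as a list (score SD 0.13, adjusted permutation p = 0.778), nor did any of the 10 tested members, 0 also adjusted over the list alone. Cd8a had 28, 53, 23 and 78 counts in tumours 1 to 4. Pdcd1 had 15 counts in tumour 3 and 0 in each of the others, and Ctla4 had 2 to 10 counts, whereas Cd274, which encodes PD-L1, had 17.7 ± 5.85 CPM (SD, n = 4).

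Cell division genes were highest in tumour 3 as groups, although no single member passed. Mitosis genes scored 0.71 in tumour 3, 0.19 in tumour 1, -0.43 in tumour 4 and -0.47 in tumour 2, with Mki67 at 713, 513, 400 and 365 CPM in that order. DNA replication genes scored 0.77 in tumour 3 and at most -0.10 in the others. The score SDs were 0.56 and 0.53, each with an adjusted permutation p of 0.000437, while 0 of 18 members in each list passed, 0 also adjusted over the list alone. The replication call was lost without tumour 3 (adjusted permutation p = 0.31). Genes induced by ERK signalling, which acts downstream of Met, scored 0.55 and 0.16 in tumours 3 and 1 and -0.32 and -0.39 in tumours 2 and 4 (score SD 0.44, adjusted permutation p = 0.0055, and 0.0696 against random lists matched also on SD). Of 15 tested members 3 passed, or 5 adjusted over the list alone. Etv5 had 459 CPM in tumour 3 and 64.5 in tumour 4 (edgeR adjusted p = 0.0147), Etv4 98.9 and 10.6 CPM (edgeR adjusted p = 0.00521) and Spry1 121 and 12.8 CPM (edgeR adjusted p = 0.00745). None of these 3 genes passed without tumour 3 (edgeR adjusted p = 0.438, 0.546 and 0.318) or tumour 4 (0.159, 0.163 and 0.423), nor Etv5 without tumour 2 (0.0916). Not all members took the order of the list score. Egr1, Areg and Fosl1, which did not pass, were highest in tumour 4, at 91.0, 10.2 and 2.08 CPM. In tumour 3 they had 24.8, 3.03 and 0.784 CPM. Mesenchymal genes scored 0.47 and 0.22 in tumours 3 and 1 (score SD 0.41, adjusted permutation p = 0.00318), and 4 of 18 passed, also 4 adjusted over the list alone. Twist1 was highest in tumour 3, Cdh2 and Foxc2 in tumour 1, and Spp1, which encodes osteopontin, in tumour 4 at 9927 CPM against 485 to 774 elsewhere (edgeR adjusted p = 4.26e-08). These calls were lost for Cdh2 and Foxc2 without tumour 1 (edgeR adjusted p = 0.298 and 1), for Twist1 without tumour 2 or 3 (0.113 and 0.428) and for Spp1 without tumour 4 (1). Mesenchymal genes were also enriched (Fisher's exact test, adjusted p = 0.0153), but not without tumour 1 or 3 (0.214 and 0.0553) or among genes with a mean of at least 5 CPM (0.0839).

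Lipid and sterol synthesis genes scored 0.49 and 0.21 in tumours 3 and 4 and -0.28 and -0.41 in tumours 1 and 2 (score SD 0.42, adjusted permutation p = 0.00321). Ribosomal protein genes scored 0.52 and 0.31 in tumours 1 and 2 and -0.26 and -0.58 in tumours 4 and 3 (score SD 0.51, adjusted permutation p = 0.00117). Hypoxia and glycolysis genes had a score SD of 0.28 (adjusted permutation p = 0.0422), a call lost when tumour 2 or 3 was left out (0.101 and 0.0609), among genes with a mean of at least 5 CPM (0.0634) and against random lists matched also on SD (0.147). In these 3 lists 0 members passed, 0 also adjusted over the list alone. The other 17 lists, the MET axis, receptors and T cells among them, did not pass, with score SDs from 0.10 to 0.36 and adjusted permutation p from 0.0619 to 0.778. They included fibroblast and matrix genes (score SD 0.27), endothelium (0.27), DNA damage response (0.25), pericytes (0.25), oxidative phosphorylation (0.14), mitochondrially encoded genes (0.20), dendritic cells (0.14), T cell checkpoint genes (0.20), Notch (0.17), immediate early genes (0.14), Wnt targets (0.12), driver genes (0.12), recruiting ligands (0.36) and BCL2 family genes (0.10). Some of these lists passed under other settings. Fibroblast genes passed without tumour 4 (adjusted permutation p = 0.0195), with library size alone (0.0442) and with medians (0.00428). DNA damage genes passed without tumour 1 or 4 (0.0496 and 0.0432), with library size alone (0.0442) and with medians (0.0275). Endothelium passed with medians (0.00247) and against random lists matched also on SD (0.0164), and pericytes and immediate early genes with medians (0.0445 and 0.0406). Recruiting ligands passed without tumour 1 (0.0194) and, as did Wnt targets, with the count minimum required in 1 library (0.0104 each). The latter setting admits genes high in 1 library alone, so passes under it are partly built in. The pericyte, dendritic cell and mitochondrial lists had 1 member past the test each, also 1 adjusted over the list alone, namely Des, Fscn1 and ATP6. Des had 124 CPM in tumour 3 and at most 6.83 elsewhere, standing apart in the same tumour as skeletal muscle genes such as Ttn (860 CPM), and did not pass without tumour 3 (edgeR adjusted p = 1). Fscn1 was lost without tumour 2 or 3 (edgeR adjusted p = 0.122 and 1) and ATP6 without tumour 1, 2 or 4 (0.109, 0.238 and 0.27). The fibroblast, endothelium, DNA damage, oxidative phosphorylation, checkpoint, immediate early and BCL2 lists had 0, also 0 adjusted over the list alone.

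**Figure D1:**
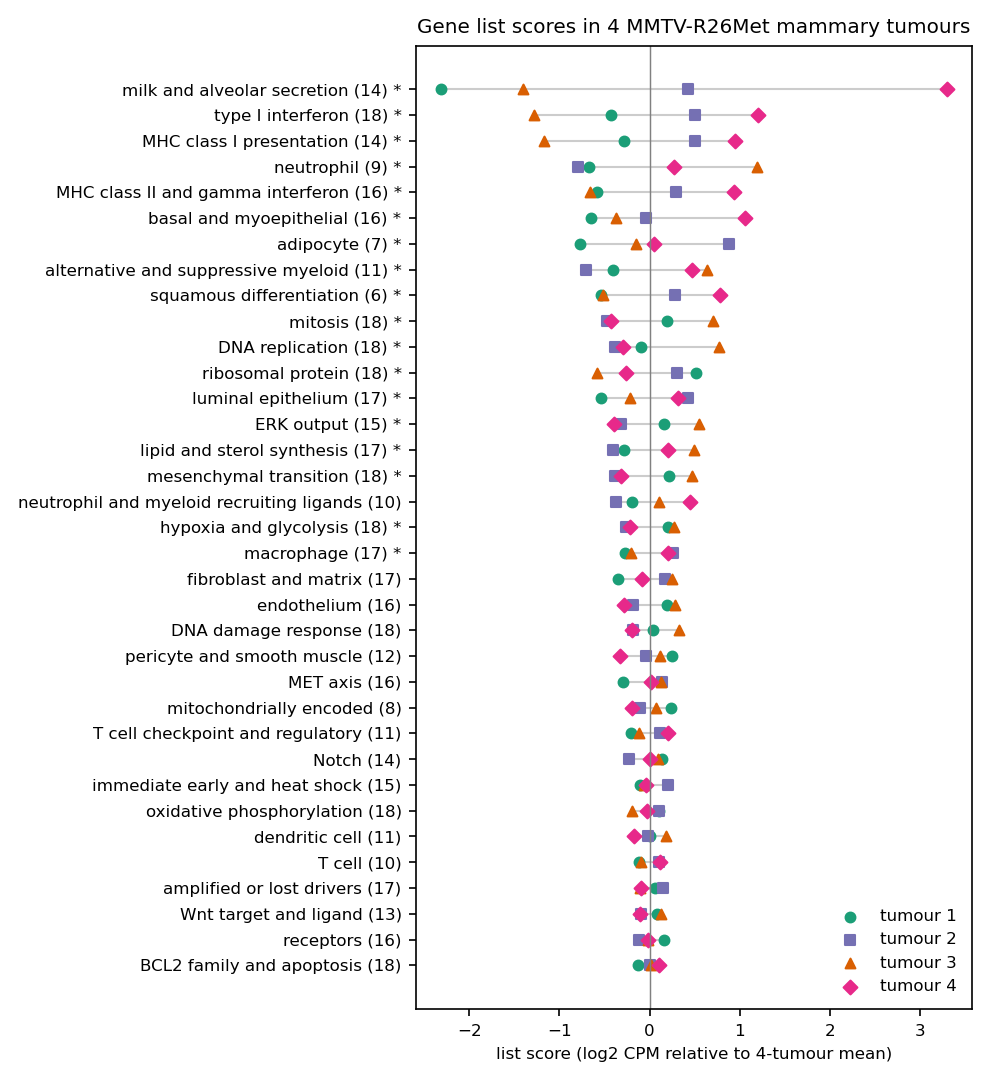
Scores of the 35 tested gene lists in each tumour. The horizontal axis gives the list score, the mean log2 CPM of the members relative to the mean over the 4 tumours, each point is 1 tumour, the number of tested members stands in brackets and a star marks an adjusted permutation p under 0.05. The milk list runs from -2.31 in tumour 1 to 3.30 in tumour 4, the widest range.

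Genes of skeletal muscle were found almost entirely in tumour 3. They took 0.248% of its counts (95% exact binomial interval 0.246 to 0.250%) and at most 0.00376% in any other tumour. Ttn, the giant sarcomere protein titin, had 860 CPM in tumour 3 and 2.01 to 6.25 in the others (edgeR adjusted p = 1.03e-37), and the fast myosin Myh4 and skeletal actin Acta1 had 12809 and 13166 counts in tumour 3 against at most 12 and 16 in any other. Only 4 of the 17 genes met the count minimum, which all 4 libraries had to reach, too few for the list test, and 3 of these passed, also 3 adjusted over the list alone. With the minimum required in 1 library, a setting chosen after the data were seen, 16 of 17 passed. The list then scored 5.52 in tumour 3 and -2.03 to -1.72 in the others (adjusted permutation p = 4e-04). Genes high in tumour 3 alone enter at that setting, so this result restates the pattern and is no separate support. Adipocyte genes scored 0.88 in tumour 2 and -0.77 in tumour 1 (score SD 0.68, adjusted permutation p = 0.0138), and 2 of 7 passed, or 3 adjusted over the list alone, with Cfd highest in tumour 2 and Fabp4 in tumour 3. Without the tumour in which it was highest, each of Cfd, Fabp4 and Ttn had edgeR adjusted p = 1. The call of the adipocyte list was lost without tumour 1 or 2 (adjusted permutation p = 0.0601 and 0.181), among genes with a mean of at least 5 CPM (0.264), without its most variable member (0.101) and against random lists matched also on SD (0.114). Lists of cytotoxic and NK cells, B and plasma cells, mast cells and eosinophils, red blood cells and Y-linked genes with Xist had 1 to 4 tested members, 0 of which passed, and were not tested as lists. Adjusted over the list alone, 1 B and plasma cell gene and 3 red blood cell genes passed. With the minimum required in 1 library, 1 of 7 red blood cell genes passed. That list then scored 1.11, 0.86, -1.35 and -0.63 in tumours 1 to 4 (adjusted permutation p = 0.00277). The cytotoxic, B cell and mast cell lists did not pass at that setting (adjusted permutation p = 0.363, 0.824 and 0.206). Xist had 1547 ± 577 CPM (SD, n = 4).

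**Figure D2:**
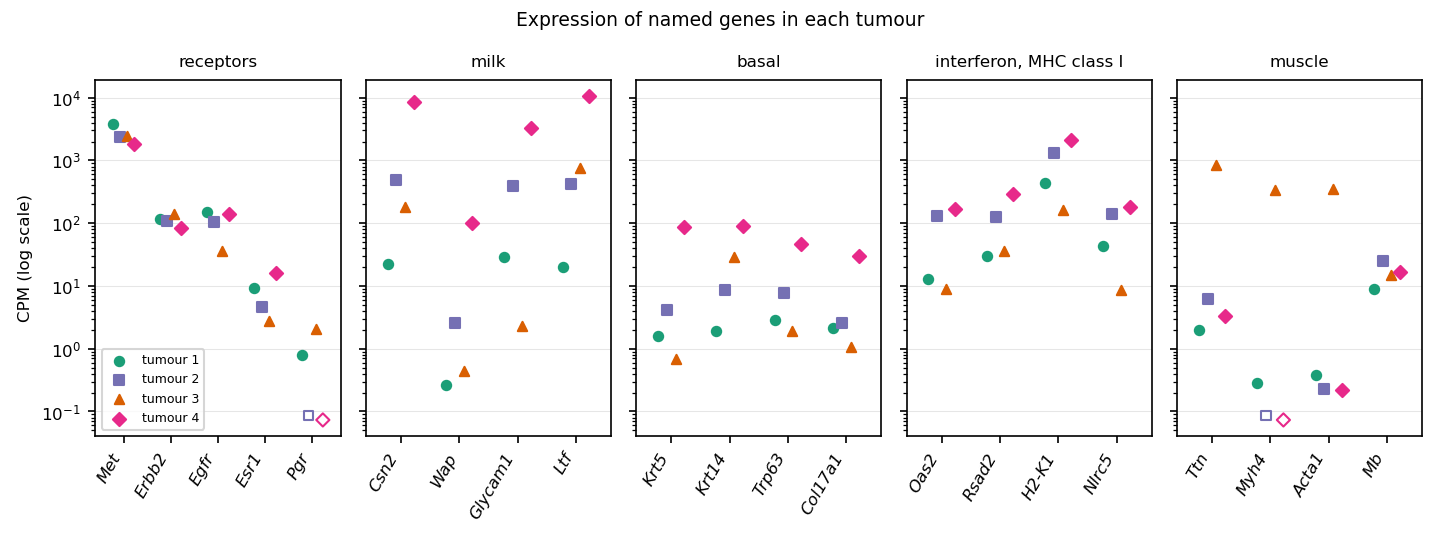
Expression of named genes in each tumour, in CPM on a logarithmic axis, with 1 point per tumour. Open symbols mark 3 counts or fewer and are drawn at the level of 3 counts, 0.0868 CPM in tumour 2 and 0.0733 in tumour 4. Csn2 and Krt5 stand highest in tumour 4, at 8476 and 87.3 CPM, and Ttn in tumour 3, at 860 CPM.

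Single genes set each tumour apart further. Tumour 1 was highest for Grb10, an adaptor of the insulin receptor, at 240 CPM against at most 27.3 elsewhere (edgeR adjusted p = 4.06e-09). The mucin Muc4 was lowest there, at 1.77 CPM against 41.0 to 342. Tumour 2 was highest for Bpifb5 (98.4 CPM, at most 2.98 elsewhere), Tnxb, a matrix tenascin, and the chitinase Chit1, and lowest for Robo2 and Cdh19. Tumour 3 was highest for the muscle calcium channel Ryr1 and for Igf2bp1, an RNA-binding protein of fetal tissue, at 130 CPM against at most 6.68 (edgeR adjusted p = 1.79e-23), and lowest for Arfgef3 and Thrsp. Tumour 4 was highest for the transcription factors Gata2 (42.5 CPM, at most 1.07 elsewhere, edgeR adjusted p = 1.48e-10) and Lhx9 (42.0 CPM, at most 0.941). It nearly lacked BC018473 (0.879 CPM against 522 to 997, edgeR adjusted p = 3.69e-16) and the keratin Krt23 (0.830 CPM against 41.5 to 214). Of the driver genes, Nf1, a negative regulator of Ras, passed with 20.95 CPM in tumour 4 and 71.4 to 155 in the others (edgeR adjusted p = 0.0171), 1 of 17, or 3 adjusted over the list alone. Lef1, of the Wnt list, had 34.7 CPM in tumour 1 and at most 4.37 elsewhere (edgeR adjusted p = 0.000525). Hey1, of the Notch list, had 56.7 CPM in tumour 1 and at most 18.3 elsewhere (edgeR adjusted p = 0.0375). Left-out tumours ended many of these calls. For genes named because 1 tumour stood apart, a loss without that tumour is largely built in. Grb10, Lef1 and Hey1 each had edgeR adjusted p = 1 without tumour 1, and without tumour 2 the values were 0.375 for Bpifb5, 0.865 for Tnxb, 0.907 for Chit1, 1 for Robo2, 0.45 for Cdh19, 0.0623 for Nf1 and 0.228 for Hey1. Without tumour 3 edgeR gave adjusted p = 0.345 for Ryr1, 1 for Arfgef3, 0.366 for Thrsp and 0.0832 for Cdh19, and without tumour 4 it gave 1 for Gata2, Lhx9, BC018473 and Nf1.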

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

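The tests of muscle RNA, of leukocyte reads (changed later from 4 lists to 8 and then split by cell class) and of gene order along chromosomes were chosen after the results were seen, and those of GC content and of the proximal and distal chromosome parts before. Single values were compared as log2 CPM, although they are printed below in CPM. A value was singled out where the gap of 1 tumour to the nearest other, as a share of the range of the 4 tumours, was large on the log2 scale. The limit was the 95% critical value of Dixon, which chance exceeds in about 1 in 20 groups. This held for 13 of 132 named genes and 0 of 35 lists, and for 5.64% of all genes tested. Many named genes were chosen because 1 tumour stood apart, so their share says little.

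In tumour 4, Spp1 had 9930 CPM (nearest other 774), Jag2 12.4 (1.96), Csn1s2b 72 (0.839) and Gata2 42.5 (1.07). Parp1 was low there with 70.3 CPM (nearest other 100), and BC018473 with 0.879 CPM (522). Tumour 3 was high for Des with 124 CPM (nearest other 6.83), Mylpf with 44.1 (0.636), Slc14a1 with 27.6 (0.415) and Neb with 253 (4.62). It was low for Car9 with 2.27 CPM (nearest other 15.9) and Atp6v0c with 2.61 (46.8). Cfd had 8.3 CPM in tumour 2 (nearest other 0.44).

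Skeletal muscle genes, Mylpf and Neb among them, stood apart in tumour 3. An immature muscle programme in place of adult muscle would place most myosin heavy chain counts on embryonic, perinatal or slow forms. Instead, 98.6% of those counts in tumour 3 lay on adult fast forms (15280 against 219 counts, 95% exact binomial interval 98.39 to 98.77%). This share does not exclude an immature part beside adult muscle. Myod1 and Myog, chosen after their values were seen, had 35 and 108 counts in tumour 3 and at most 1 elsewhere. In all 16 of 17 list members were at least 10-fold above the highest other tumour, with a median of 171-fold and Mb, at 0.599-fold, as the exception, but any source of muscle RNA would give this. Whether muscle was cut out with the tumour therefore stays open, and the design has no group that bears on it.

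Interferon response and MHC class I genes were higher in tumour 4 than in tumour 3 by 2.49 and 2.14 on the log2 scale, with the count minimum required in 1 library so that scarce leukocyte genes are included. A bias with GC content and transcript length is argued against, since with the minimum in all libraries the 17 interferon genes of known GC content and length differed by 2.52 before and 2.55 after that trend was removed, which took 0.5% of the variance over genes. Myeloid cells present in different amounts are argued against as well, since among genes with a mean of at least 5 CPM the median difference was 0.24 for 16 macrophage, -0.34 for 7 suppressive myeloid, -0.6 for 7 neutrophil and -0.06 for 6 dendritic cell genes, with upper quartiles of at most 0.59 (means over all members 0.44, 0.21, -1.18 and -0.1). Lymphocytes and mast cells stay open, because only 3 of their genes were that abundant: their lists differed by 1.05 (mast cells and eosinophils), 0.93 (cytotoxic and NK cells), 0.75 (T cells) and 0.17 (B and plasma cells), while the pan-leukocyte gene Ptprc, chosen after its values were seen, had 78.5 CPM in tumour 3 and 76 in tumour 4. The signal that induced the genes was not measured, and no biological explanation was tested.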

How the results depend on the processing

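The count cutoff needed in at least 1 library was chosen after seeing the data, and the other alternatives earlier. The 574 genes past the test became 895 with no count filter (23632 genes tested, 441 shared) and 945 with the cutoff in at least 1 library (18870 tested, 473 shared), both of which test more genes. Holm adjustment, stricter by construction, left 198, and DESeq2 dispersion outliers numbered 91, for which the cause was not tested. Leaving out 1 tumour gave 367 (without tumour 4) to 417 genes, with fewer samples. RLE and library size scaling gave 576 each, a mean of at least 5 CPM 494, and leaving out milk, fat, muscle and the 100 most abundant genes 564. The 8 enriched lists became 3 without tumour 3 and 10 without tumour 1. The median Spearman correlation of tumour pairs was 0.944 and, at a mean of at least 5 CPM, 0.897, for which the cause was not tested. Lists past the score test numbered 15 to 24 over the alternatives, against 18. Over single lists and settings, 411 score calls stayed on their side of the threshold, 26 were lost and 16 gained. Over named genes, 986 calls stayed, 57 were lost and 1 gained, the losses and the gain all with a tumour left out. The prior count does not enter the gene test. Its settings could therefore not change these calls, and they add to the 986 without testing them. Spreads and counts have no direction, but with the cutoff in at least 1 library some small scores turned sign, such as squamous genes in tumour 2 (0.28 to -0.18) and adipocyte genes in tumour 4 (0.05 to -0.22); more members enter there. Depth limits genes such as Pdcd1, Ctla4 and Pgr, with at most 79 counts in any library. No paired analysis was possible because the tumours form 1 group.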

Other observations

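The genes in these first 2 paragraphs, the tests of gene order and the 60 Mb limit on chromosome 5 were chosen after the values were seen. Some imprinted genes were highest in tumour 3, the tumour in which skeletal muscle genes stood apart as well (list score 5.52 with the count minimum required in 1 library); no list of such genes was tested. Mest had 317 CPM there and at most 6.79 elsewhere (edgeR adjusted p = 2.13e-25), and H19, an imprinted long non-coding RNA, had 131 CPM and 9.55 to 48.1 elsewhere (edgeR adjusted p = 0.000455). Igf2, the growth factor next to H19 on chromosome 7, had 1161 counts in tumour 3 and 2 to 17 in the others, too few for the test. Peg10 was high in tumours 3 and 4 (33.1 and 27.5 CPM, at most 4.1 elsewhere, edgeR adjusted p = 0.000525). Grb10 instead was highest in tumour 1, at 240 CPM. Without tumour 3 Mest and H19 did not pass (edgeR adjusted p = 1 and 0.143), nor H19 and Peg10 without tumour 2 (0.438 and 0.15) or Grb10 without tumour 1 (1). Peg3 did not pass, at 437 CPM in tumour 3 and 89.9 to 246 CPM elsewhere (edgeR adjusted p = 0.175), nor did Igf2bp2 (23.1 CPM in tumour 3, edgeR adjusted p = 0.169) or Hmga2 (9.15 CPM, edgeR adjusted p = 0.436).

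Some Wnt pathway genes below the count minimum also stood out in tumour 3. Sp5 had 264 counts there and at most 1 elsewhere, Notum 50 and 0, and the ligand Wnt6 151 and at most 6. Lef1, the 1 Wnt list member past the test with the minimum in all libraries, was instead highest in tumour 1. It had 34.7 CPM there and 3.53 CPM in tumour 3. With the count minimum required in 1 library, 5 of 17 Wnt genes passed (edgeR, adjusted over all genes tested). The list then scored 0.88 in tumour 3 (adjusted permutation p = 0.0104). With the minimum in all libraries it scored 0.13 there and did not pass (adjusted permutation p = 0.771). Sp5, Notum and Wnt6 entered the former setting through tumour 3 alone, so its result restates their counts and is no separate support. Transcripts of the interferons Ifng, Ifnb1 and Ifne were near the limit of detection, and other interferon genes were not looked at. Ifng had 7 counts in tumour 4 and 0 in the others. Ifnb1 had 6, 4, 2 and 1 counts and Ifne 1, 0, 1 and 5 counts in tumours 1 to 4. Aldh1a3, an aldehyde dehydrogenase, ran from 8.0 CPM in tumour 1 to 104 in tumour 4 (edgeR adjusted p = 0.000777, and 0.984 without tumour 1). Of 4 genes near BC018473 on chromosome 11, St6galnac2 was low in tumour 4, at 15.9 CPM against 142 to 200 (edgeR adjusted p = 0.000777, and 1 without tumour 4), while Sphk1 (0.229), Snhg16 (1) and Mxra7 (1) did not pass.

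Genes of a chromosome tended to be shifted together within a tumour. The median log2 deviation of chromosome 4 was -0.25 in tumour 3 and 0.26 in tumour 4, that of chromosome 16 was -0.28 in tumour 1 and 0.28 in tumour 3, and 11 of 80 medians lay beyond 0.2. Rotating gene order against chromosome borders argues against local order alone (permutation p = 5e-04, the smallest that 2000 rotations give, mean absolute median 0.117 against 0.09 in the median rotation and 0.116 in the highest), and removing the trend with GC content and length kept 100.9% of the shift. Different numbers of chromosome copies may account for it as a hypothesis, since medians of the proximal and distal parts correlated across 20 chromosomes with r of at least 0.91 in each tumour, while the lowest r over tumours had a median of 0.312 over 2000 rotations of gene order (permutation p = 0.001, highest 0.91). DNA was not measured, and regional regulation of expression stays open.

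Shifts of parts of chromosomes were seen too. On chromosome 5, 183 genes before 60 Mb had a median of 0.5 in tumour 3 and -0.33 in tumour 4, while 527 genes after it had 0.13 and 0.02. The largest of 545 windows of 40 genes lay on chromosome 13 from 21179450 to 23683959 (GRCm38), a region with many histone genes, with a median of 0.74 in tumour 3.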
